A study of Mus musculus with 1119 samples.

How the data were processed

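The values are the authors' deposited TPM in 3 tables, 1 for the P21 to P27 cells and 1 each for the P30 hair bulb and the P30 dermal papilla, with 46609 rows each and the same rows in the same order. Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.9 to mm10 and quantified with RSEM 1.2.30. The fields of the dermal papilla table are parted by a slash and a letter t in place of a tab, and were read as such. Every column summed to 1000000 within rounding (999999.02 to 1000000.77), 92 rows were ERCC spike-ins, and 83 symbols stood on several rows, which were kept apart by their identifiers. All 1119 columns matched a sample. Read depth is not recorded in TPM, so no measure of depth per cell was used, and the median number of genes at a TPM of 1 or more ran from 5367.5 to 7392.5 between groups. Median shares of TPM on 8 ribosomal RNA rows ran from 54.5% to 76.8%.

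Each sample is 1 cell. The labels name no animal, so each group of cells counted as 1 sample, no test, p-value or standard error was computed, and plates, read from the start of each title, were shown only as a technical spread. The letters b, hg and mat of the titles are not expanded there, and the authors' annotation of 6 types gives bulge, hair germ and matrix. The 2 P30 tables hold 1 type each, so no comparison between types could be made within them.

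For each comparison the size is the difference of the 2 groups' mean log2(TPM + 1). Mean TPM of both groups and the share of cells at a TPM of 1 or more are given beside it, with an exact binomial (Clopper-Pearson) interval at 95% for the share. Gene lists were summarised by the median of their members. The percentile of that median was taken among 10000 random lists of the same size, drawn from 20 bins of mean expression. The median gene is the median over genes at a TPM of 1 or more in at least 30% of the cells of 1 of the 2 groups, without spike-in, ribosomal RNA and mitochondrial rows. Spreads by plate set each plate of 10 or more cells against the whole other group. Krt85 and 1 gene of differentiated interfollicular epidermis have no row and were not analysed here.

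Genes were named by a rule set before the data were examined, as were the 37 gene lists and the planned comparisons. For each comparison, the rule takes the 8 genes with the largest difference in each direction, seen in at least 30% of the cells of 1 group and with the same sign in every plate of 10 or more cells, without predicted models and genes used in the sort. It adds up to 4 members with the largest absolute difference of each list described. For the authors' types, it takes the 4 genes with the largest gap to the highest other type, seen in at least 50% of the type's cells. Some genes that the rule takes are not named in the text. Ligands and receptors were given as levels by type, and those named were chosen for their level after the values were seen. The comparison of P30 with P25 to P27 matrix cells, the list of ribosomal RNA rows, the numbers of markers that define a class of cells, a list of 10 muscle progenitor genes, and the clusters were added after the data were seen.

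Cells of each P30 table with at least 2000 genes were clustered after leaving out spike-in, ribosomal RNA and mitochondrial rows and rescaling to 1000000. Pseudogenes, ribosomal protein genes and predicted models were passed over, and the 1500 genes with the largest variance for their bin of mean expression gave 15 principal components. A graph of 15 shared neighbours was partitioned by the Leiden method at a resolution of 0.8, and at 0.4 and 1.2 for comparison, with a fixed seed. A first version with genes scaled to equal variance, run on all 3 tables at the same 3 resolutions, was looked at before this one, and its values are not used here. Gene positions and biotypes came from GENCODE release M21 on GRCm38, the assembly named mm10.

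The 4 comparisons of P21 to P27, with random lists, and the clusters of the 2 P30 tables, were also run on simulated data, after the measured values had been seen. The P30 comparison, gaps between types, shares of cells and marker classes were not. Cells of both groups of a comparison were mixed and dealt out again at the real sizes, and 200 genes of the first set were changed by known folds, 50 for each fold. For P21 bulge against germ (8316 genes), genes raised 4-fold gave a median difference of 1.24, with 100% of the right sign, and genes raised 2-fold 0.66, with 88%. For P23 to P24 against P21 germ (8753 genes) the 2 folds gave 1.19 (100%) and 0.50 (92%), for P25 to P27 matrix against P23 to P24 germ (8139 genes) 1.12 (100%) and 0.71 (100%), and for P25 to P27 matrix against germ (7715 genes) 1.03 (94%) and 0.45 (78%). In these runs the median differences of raised genes lay below the log2 of the planted fold. Unchanged genes had a standard deviation of 0.40, 0.37, 0.27 and 0.52 in the same order, from the dealing of cells alone. Of 200 random lists of 18 genes, 6.50%, 3%, 4.50% and 8% fell outside the middle 95% of 1000 matched lists.

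For the clusters, every gene's values were shuffled over the cells of a P30 table (46474 rows). Without planted groups the method still gave 7 clusters in the hair bulb and 5 in the dermal papilla, so a number of clusters is no evidence of structure. With 3 planted groups and 200 genes raised 4-fold, the groups were not recovered (adjusted Rand index 0.00870 and 0.0144), and at 16-fold they were (0.992 and 0.980). The first principal component held 14.4% of the variance of the measured hair bulb values and 0.654% of the shuffled ones, and 4.28% and 0.712% for the dermal papilla.

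Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.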

Results

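Single cells of mouse back skin were followed from the resting follicle at postnatal day 21 (P21) to the growing follicle at P30. Per the authors' annotation, the sorted cells were 39 telogen bulge stem cells, 71 telogen hair germ cells, 89 first-stage anagen hair germ cells (73 at P23 to P24 and 16 at P25 to P27), second-stage matrix cells (55, 76 and 68 on 3 plates at P25 to P27), P30 matrix cells of the hair bulb (76, 78, 75, 74 and 81 on 5 plates) and P30 dermal papilla cells (87, 87, 86 and 77 on 4 plates), 1119 cells in all. No label named the animals, so each group counted as 1 sample and no difference between groups was tested. Differences are of mean log2(TPM + 1), and intervals of shares cover the counting of cells only.

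At P21 the bulge and the hair germ beneath it differed in single genes and in lists of signal-response genes. Bulge cells carried Dmkn, which encodes a secreted epithelial protein, Postn, a matricellular protein, Krt6a and Krt24, keratins of the outer layers and of the bulge, and Angptl7, a secreted angiopoietin-like protein. Hair germ cells carried Rasgef1b, an exchange factor for small GTPases, Dusp6, a phosphatase induced by FGF and ERK signals, Foxi3, a transcription factor of placodes and hair germ, and Mfap2, a microfibril protein. Fst and Grem1, antagonists of BMP ligands, were higher in the bulge. Targets of hedgehog signals, Gli1 and Ptch1, were higher in the germ.

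Dmkn had a mean TPM of 900 against 149.1 in bulge and hair germ cells (log2 difference 6.29) and was seen in 100% (91 to 100) against 46.5% (34.5 to 58.7) of cells. Postn stood at 384.5 against 53.4 (5.67; 100% against 40.8% of cells), Krt6a at 246.5 against 51.9 (5.17; 84.6% against 14.1%), Angptl7 at 180.7 against 15.3 (4.96; 89.7% against 16.9%) and Krt24 at 121.3 against 18.7 (4.56; 92.3% against 16.9%). S100a4, a calcium-binding protein, Sbsn, an epidermal secreted protein, and Prss23, a serine protease, followed with differences of 4.61, 4.33 and 4.27. In the other direction, Rasgef1b stood at 3.25 in the bulge (-5.06; 23.1% against 88.7% of cells), Mfap2 at 11.4 against 99.6 (-4.03), Dusp6 at 7.92 against 86.8 (-4.00; 17.9% against 77.5%) and Foxi3 at 6.64 against 70.7 (-3.93; 10.3% against 74.6%). Slc38a4, an amino acid transporter, Ly6e, a cell surface protein, Tspan18, a tetraspanin, and Adamts1, a secreted protease, gave -3.87, -3.82, -3.81 and -3.65. The median of 8847 expressed genes was lower in the bulge, at -0.21.

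The 18 bulge genes had a median difference of 1.49 (1.69 above the median gene; 15 higher, 3 lower, percentile 100 among matched random lists), and 12 of them were at least 1 higher. The 10 hair germ genes had a median of -1.21 in the bulge (7 lower, 3 higher, percentile 0), with Runx1, a transcription factor of follicle activation, at -2.27. Fst, a follistatin listed with the germ, went the other way at 3.69 (110.3 against 28.2; 92.3% against 42.3% of cells). The 8 FGF response genes were all lower in the bulge (median -1.15, percentile 0): Etv4 and Etv5, transcription factors downstream of ERK, and Spred2, an inhibitor of that pathway, gave -3.18, -1.54 and -1.41. Hedgehog response genes had a median of -1.81, with Gli1 at -2.06 (30.8% against 71.8% of cells) and Ptch1 at -1.81, while Hhip, a hedgehog-binding protein, was seen in 1 bulge cell and no germ cell.

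WNT response genes were lower in 9 of 11 cases (median -0.53): Tcf7, a TCF family factor, gave -1.89, Axin2, a negative-feedback scaffold, gave -1.84, and Notum, a secreted WNT deacylase, was listed at 0 in every bulge cell and at a mean TPM of 14.7 in the germ. BMP response genes tilted to the bulge (median 0.49; 6 of 8 higher, percentile 99.9) through Id2, an inhibitor of bHLH factors, at 2.58 and Smad9, a receptor-regulated SMAD, at 1.31, while Id1, another of the Id family, gave -0.64. BMP inhibitors were higher there too (median 0.69; 6 of 10 higher, percentile 100): Grem1 stood at 44.5 against 7.14 (3.36; 84.6% against 21.1% of cells), Sostdc1, a secreted modulator of BMP and WNT, at 53.9 against 20.1 (2.37) and Nog, noggin, at 5.86 against 1.26 (1.39). Outer root sheath genes were higher in 9 of 11 cases (median 0.76), with Barx2, a homeobox factor, at 2.52, Cxcl14, a chemokine, at 2.17 and Sox9, a stem cell factor of the bulge, at 1.55. Cd34 (6.09) and Lef1 (-2.84) parted as their use in the sort requires and are a check of the labels. List medians and percentiles were taken without leaving out genes used in the sort, so they are not fully independent of it. Each group came from 1 plate, so no spread between plates exists here.

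**Figure D1:**
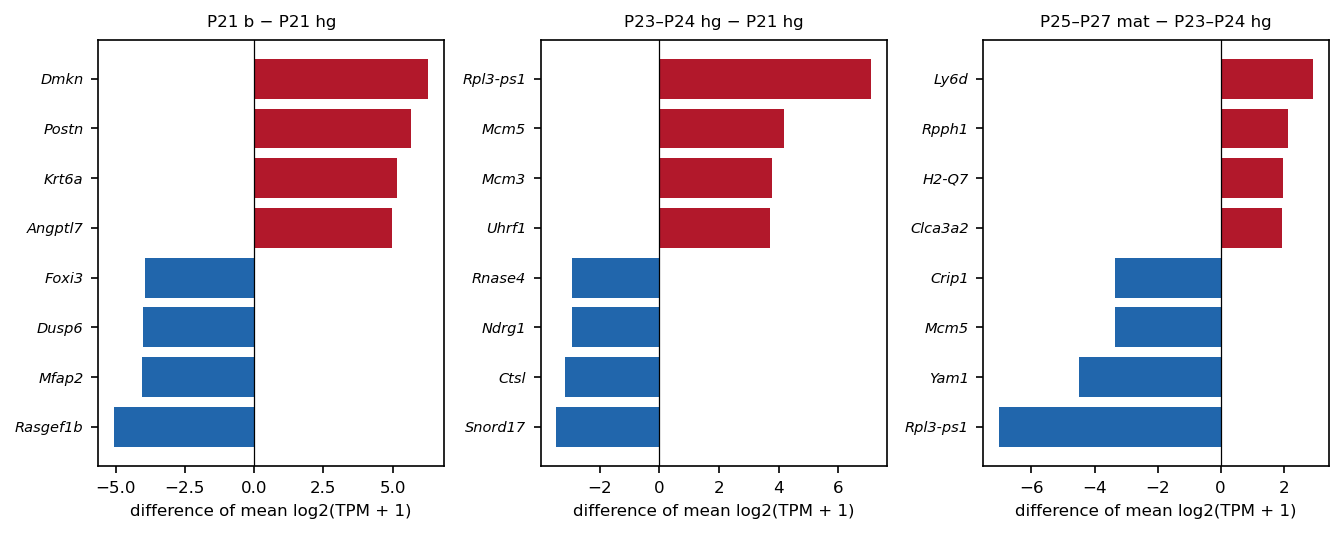
The 4 genes with the largest difference in each direction for 3 comparisons of the P21 to P27 cells. Bars are differences of mean log2(TPM + 1).

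Between P21 and P23 to P24, hair germ cells took up genes of DNA replication and division. Mcm5, Mcm3 and Mcm2 encode parts of the replicative helicase, Uhrf1 carries DNA methylation through replication, Pold1 is a catalytic subunit of DNA polymerase delta, and Cdk1 drives entry into mitosis. Genes of the resting germ fell, among them Ctsl, a lysosomal protease, Ndrg1, a gene of stress and differentiation, and Mfap2. Lgr5, a receptor for R-spondins and a mark of follicle stem cells, and Krt15, a basal keratin of the bulge, fell as well.

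Mcm5 went from a mean TPM of 0.907 to 51.9 (log2 difference 4.17), in 80.8% (69.9 to 89.1) against 8.45% (3.16 to 17.5) of cells at P23 to P24 and P21. Mcm3 gave 3.78 (71.2% against 5.63% of cells), Uhrf1 3.70 (74% against 23.9%), Pold1 3.61 (78.1% against 15.5%), Mcm2 3.43 (82.2% against 31%) and Cdk1 3.21 (49.3% against 1.41%). Psat1, an enzyme of serine synthesis, gave 3.50. All 18 S phase genes were higher (median 2.48), and so were all 20 G2/M genes (median 1.42, 1.48 above the median gene, percentile 100), with Top2a, a topoisomerase, at 2.76, Ccna2, cyclin A2, at 2.47 and Mki67 at 2.06. The largest difference belonged to Rpl3-ps1, a processed pseudogene of a ribosomal protein, listed at 0 in every P21 hair germ cell and at a mean TPM of 200.9 at P23 to P24.

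Ctsl fell by 3.16 (11.3 against 119.4 at P23 to P24 and P21), Ndrg1 by 2.93, Rnase4, a secreted ribonuclease, by 2.91, Anxa8, an annexin, by 2.83, Mfap2 by 2.75, Sepp1, a selenium carrier, by 2.68 and Dtx3, a Deltex family ligase, by 2.65. Snord17, a small nucleolar RNA, fell by 3.45. Bulge genes were lower in 15 of 18 cases (median -0.61, percentile 0.02): Dkk3, a secreted Dickkopf protein, fell by 1.97, Krt15 by 1.21 (1551 against 2351) and Id2 by 1.19. Hair germ genes fell in 7 of 10 cases (median -0.44, percentile 5.50), with Runx1 at -1.34 and Msx2, a homeobox factor, at -1.03; Lgr5 gave -1.46 and Lef1 -1.72, both used in the sort. Receptors fell in 30 of 39 cases (median -0.31): Fgfr3 and Fgfr1, receptor tyrosine kinases for FGFs, gave -1.54 and -1.31. Keratinocyte genes fell in 9 of 10 (median -0.53, percentile 8.52), led by the hemidesmosome genes Col17a1 (-1.47) and Itgb4 (-1.01). The 4 hedgehog response genes had a median of 0.39 (percentile 91.3; Ptch1 0.72), and Gli1 among them turned from 0.23 to -0.19 as the log2 ratio of mean TPMs. Each age came from 1 plate, so age and plate cannot be told apart.

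**Figure D2:**
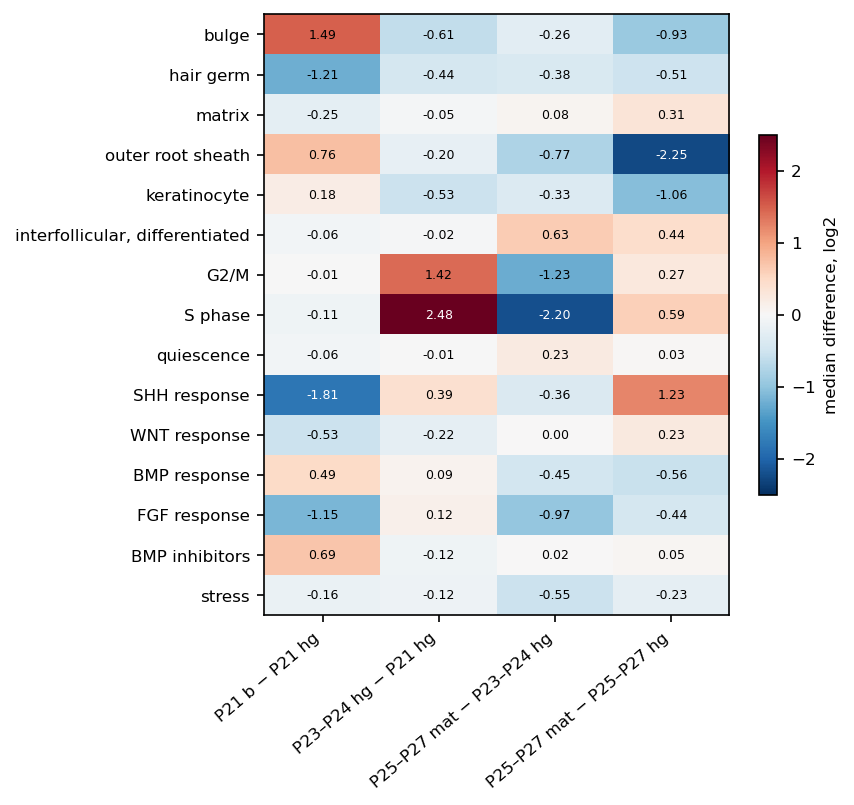
Median difference of each gene list in the 4 comparisons of the P21 to P27 cells, as the first group minus the second (log2).

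Matrix cells at P25 to P27 had fewer transcripts of division than the hair germ at P23 to P24, and more of Ly6d, a surface protein of differentiating epithelia, H2-Q7, an MHC class I gene, Ank, a pyrophosphate transporter, and Krt80, an epithelial keratin. Cdkn1a, the cell cycle inhibitor p21, was higher. Response genes of FGF and BMP signals, Etv4, Dusp6, Id1 and Id3, were lower. Age, sort and plate change together in this comparison, as all P23 to P24 germ cells came from plate 902hg. That plate also differed from the matrix plates in the pseudogene Rpl3-ps1, seen in 93.2% of its cells against 1.32% to 2.94%.

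Ly6d stood at 276.1 against 18.3 (log2 difference 2.94; 44.7% (37.7 to 51.9) against 13.7% (6.77 to 23.8) of cells), H2-Q7 at 36.8 against 6.74 (1.99; 51.3% against 15.1%), Ank at 74.2 against 12.9 (1.91; 72.9% against 47.9%) and Krt80 at 35.1 against 8.33 (1.85). Clca3a2, a chloride channel regulator, and Nrep, a neuronal regeneration protein, gave 1.94 and 1.76, and Rpph1, the RNA of RNase P, gave 2.13. On the other side, Rpl3-ps1 gave -7.03, the ribosomal RNA row Yam1 -4.48, Mcm5 -3.35, Uhrf1 -3.23, Rfc5, a clamp loader subunit, -3.00, Tk1, thymidine kinase, -2.95, Hist1h2ap, a replication-dependent histone, -3.02 and Crip1, a LIM protein, -3.35.

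All 20 G2/M genes were lower in the matrix (median -1.23; -0.93 from the median gene, percentile 0; -1.41 to -1.15 by plate), with Cdk1 at -2.75, Top2a at -2.19, Ccna2 at -2.11 and Mki67 at -1.68, and so were all 18 S phase genes (median -2.20; Rrm2, a ribonucleotide reductase subunit, -2.78). Matrix genes barely moved: 8 of 14 were higher (median 0.08; 0.37 above the median gene, percentile 98.8; -0.06 to 0.17 by plate), among them Prdm1, a transcriptional repressor, at 0.82 and Ovol1, a zinc finger factor, at 0.63, against Dlx3, a homeobox factor of the hair shaft, at -0.91. Bulge genes were lower in 12 of 18 cases, but their median of -0.26 lay 0.04 above the median gene, which was itself at -0.30 (percentile 26.2; -0.47 to 0.12 by plate), with Id2 at -1.22, Dkk3 at -0.93 and Foxc1, a forkhead factor of quiescent stem cells, at 0.91.

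FGF response genes fell in all 8 cases (median -0.97; Etv4 -2.44, Dusp6 -2.24, Etv5 -1.72, Spry1, a Sprouty inhibitor, -1.06), and BMP response genes in all 8 (median -0.45, percentile 1.35; Id3 -2.32, Id1 -2.16). Outer root sheath genes were lower in 10 of 11 cases (median -0.77), with Cxcl14 at -2.79 and Krt5, a basal keratin, at -1.13; Krt14 (-2.45) and Lgr5 (-2.05) were used in the sort. Quiescence genes rose in 7 of 10 (median 0.23, percentile 99.9; -0.04 to 0.27 by plate), with Cdkn1a at 1.38 (59.4 against 12.5), Foxo3, a forkhead factor, at 0.89 and Txnip, a thioredoxin inhibitor, at 0.70, while Egr1, an immediate early gene, gave -0.73. Genes of differentiated interfollicular epidermis were higher in 5 of 6 cases (median 0.63; 0.09 to 1.03 by plate): Krtdap, a differentiation peptide, stood at 226.2 against 1.81 in 17.6% against 4.11% of cells and Krt10, a suprabasal keratin, at 137.9 against 2.41 in 51.3% against 41.1%. Of the matrix cells, 13.6% carried at least 3 of these 6 markers, against 8.22% of the germ cells.

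At the same age of P25 to P27, matrix cells differed from the remaining hair germ cells by hedgehog targets and by the loss of outer root sheath and stem cell genes. Higher in the matrix were Smoc2, a matricellular protein, Cux1, a homeobox factor of the matrix and inner root sheath, Apcdd1, a WNT inhibitor, Nrp2, a semaphorin receptor, and Gli1. Lower were Krt15, Postn, Sfrp1, a secreted WNT antagonist, and Aqp3, a water and glycerol channel. Only 16 germ cells stand behind this comparison, 14 from 1 plate and 2 from another.

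Ly6d gave 3.59, Smoc2 2.85 (38 against 1.21; 63.3% against 12.5% of cells), Cux1 2.54 (45.5 against 1.17), Apcdd1 2.43 (54.3% against 0%), Nrp2 2.40 (54.3% against 6.25%), Stmn1, a microtubule regulator, 2.29, Ctsl 2.28 and Ly6e 2.23. Without plate 913hg, which leaves 2 germ cells, Stmn1 gave -1.31 and the matrix list a median of 0.78. Lower in the matrix were Lgals1, galectin 1, at -4.77 (23.7 against 140.5; 35.2% against 93.8%), Yam1 at -4.38, Crip1 at -4.30, Aqp3 at -3.96 (57.8% against 100%), Mt2, a metallothionein, at -3.80, Ecm1, an extracellular matrix protein, at -3.79, Ces2g, a carboxylesterase, at -3.62 and Cxcl14 at -3.51. Matrix genes were higher in 10 of 14 cases (median 0.31, percentile 96.5; 0.17 to 0.53 by plate), with Prdm1 at 1.21. All 4 hedgehog response genes were higher (median 1.23; Gli1 1.25). Bulge genes were lower in 13 of 18 (median -0.93; Postn -3.42, Krt15 -2.94, Sfrp1 -2.53, Sox9 -2.17), outer root sheath genes in 9 of 11 (median -2.25) and keratinocyte genes had a median of -1.06 (Krt5 -2.25, Col17a1 -1.84). All 20 G2/M genes were higher in the matrix, by a median of 0.27.

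Mki67, a nuclear protein of cycling cells, followed the same course in shares of cells. No bulge cell at P21 held it (0% (0 to 9.03)), nor did any of the 16 hair germ cells at P25 to P27 (0% (0 to 20.6)). It was seen in 4.23% (0.880 to 11.9) of hair germ cells at P21, 47.9% (36.1 to 60) at P23 to P24 and 12.6% (8.30 to 18) of matrix cells at P25 to P27, where the 3 plates gave 0%, 10.5% and 25%. In the P30 cells, which come from other strains and tables, it was seen in 53.6% (48.5 to 58.7) of matrix cells and 4.15% (2.29 to 6.87) of dermal papilla cells.

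**Figure D3:**
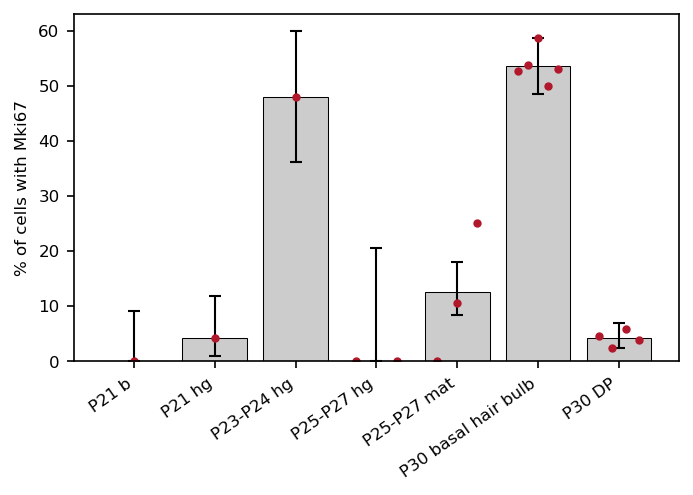
Share of cells with Mki67 at a TPM of 1 or more, with exact binomial intervals. Points are plates, and strains and ages differ between the P30 groups and the others.

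The authors' 4 types of the P21 to P27 cells set each population against the mean of the other 3. Telogen bulge cells stood out by bulge genes (median 2.196, 16 of 18 higher, percentile 100) and outer root sheath genes (1.93), and by low hedgehog (-1.93) and WNT response genes (-0.88). Telogen hair germ cells had more hair germ genes (0.83; 8 of 10 higher, percentile 100) and WNT response genes (0.91), though hair germ genes lay at -0.06 against the highest other type. In first-stage anagen germ cells all 20 G2/M genes were higher (median 1.11; -0.13 to 1.37 by plate), while hair germ genes were level (0.05, percentile 54.1). Second-stage matrix cells had little gain of matrix genes (0.04, percentile 99.3; -0.04 to 0.29 by plate), more differentiated interfollicular genes (0.47), and fewer outer root sheath (-1.58) and bulge genes (-1.22). Hedgehog response genes were at 0.66 in second-stage matrix (0.49 to 0.86 by plate), at 0.69 in first-stage germ (-0.69 to 1.06 by plate) and at 0.41 in telogen germ cells (percentile 88). FGF response genes were higher in first-stage germ (0.70; 8 of 8) and telogen germ cells (0.70; 7 of 8).

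Among single genes, the gap to the next highest type was largest for Angptl7 (4.96; 180.7 against 15.3 TPM), Krt6a (4.94), Dmkn (4.91) and Krt24 (4.56) in the telogen bulge. Ctsl (2.31), Abi3bp, an extracellular matrix protein (2.29; 74.2 against 15.5), and Mfap2 (2.04) stood out in the telogen germ. Uhrf1 (2.57), Yam1 (2.49), Rfc5 (2.48) and Mcm2 (2.36) led the first-stage germ, and H2-Q7 (1.83), Apcdd1 (1.43; 18.1 against 4.80), H2-K1, an MHC class I gene (1.26), and Ank (1.22) the second-stage matrix. Without plate 902hg, which holds all P23 to P24 cells, the gap of Uhrf1 in first-stage germ was -0.46, of Rfc5 0.12 and of Mcm2 0.10. The types and these values come from the same cells, so the gaps describe the types and are no independent evidence for them.

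By P30 the matrix of the hair bulb expressed genes of the matrix, medulla and inner root sheath that were low or absent in the P25 to P27 matrix. Padi3, an enzyme that citrullinates trichohyalin in the medulla and inner root sheath, Krt75, a keratin of medulla and companion layer, and Foxq1, a factor needed for the medulla, rose with Dlx3, Msx1 and Msx2, homeobox factors of the matrix. Gpnmb, a melanosomal glycoprotein, rose as well. Krt15, Lgr6, a stem cell receptor of the upper follicle, and Dmkn were lower. The 2 groups differ in strain, sort and table as well as age, and the comparison was added after the data were seen.

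Padi3 was listed at 0 in every P25 to P27 matrix cell and reached a mean TPM of 85.2 at P30. Gpnmb stood at 507 against 0.998 (log2 difference 5.71; 69.3% against 5.03% of cells), Krt75 at 96.7 against 1.67 (4.07), Foxq1 at 52.2 against 1.26 (3.33), Dlx3 at 73.4 against 5.14 (4.69), Msx1 at 27.1 against 1.93 (3.32) and Msx2 at 33.2 against 3.65 (3.30). Tchh, trichohyalin, Krt28 and Krt25, keratins of the inner root sheath, gave 2.81, 2.26 and 2.19, while Gata3, a factor of that sheath, gave -3.67. The median gene was 0.34 higher at P30. Medians were 1.61 for matrix genes (12 of 14 higher), 2.95 for the medulla, 1.34 for the inner root sheath, 1.31 for G2/M genes (20 of 20; Ccnb1, cyclin B1, 1.75; Ube2c, a mitotic ubiquitin enzyme, 1.70) and 0.90 for the BMP response (8 of 8; Bambi, a BMP pseudoreceptor, 2.79). Genes of the cuticle and cortex of the hair shaft rose less (median 0.45, 16 of 17 higher, 7 of them by at least 1). Companion layer genes were lower in 5 of 6 cases (median -0.35). Dermal sheath genes were higher too (median 0.50, 9 of 10, percentile 99.9), and 12.5% of the P30 cells had under 6 of 10 keratinocyte markers.

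Krt15 fell to 48 from 1198 (-6.88), Anxa8 gave -5.57, Anxa2, an annexin, -5.11, Cav1, caveolin 1, -5.04, Capns2, a calpain subunit, -4.82, Lgr6 -4.78 (9.90% against 82.9% of cells), Rpph1 -4.67 and Dmkn -4.46. Medians were -1.10 for bulge genes (Nfatc1, a calcineurin-dependent factor of quiescence, -2.86), -1.81 for the outer root sheath and -1.55 for keratinocyte genes (Krt5 -3.97). Melanocyte genes had a median of 1.44, with Dct, a pigment enzyme, at 73.2 against 1.08 in 74.7% against 10.1% of cells, Pmel, a melanosome fibril protein, at 1.91 and Tyrp1, a pigment enzyme, at 1.84; Mlana, a melanosomal membrane protein, was listed at 0 in the P25 to P27 cells. Among the largest rises, beside that of Gpnmb, were processed pseudogenes of ribosomal proteins: Rpl34-ps1 (8.48), Rps2-ps10 (7.24), Rpl3-ps1 (7.24), Rps3a3 (5.60) and 3 rows of Rpl35a with equal values (Rpl35a-ps6, 5.47).

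Ligands sorted by population. Dermal papilla cells were the main source of R-spondins, which amplify WNT signals, of FGF7 and FGF10, which act on epithelium, and of the modulators Wif1 and Sostdc1. P30 matrix cells expressed Kitl, the ligand of the melanocyte receptor Kit, and Wnt5a, Wnt4 and Wnt3. Bulge cells expressed secreted antagonists, and telogen hair germ cells Pdgfa, a growth factor for dermal cells, and Cxcl12, a chemokine. Levels are set side by side across 3 tables of different strains and ages.

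In dermal papilla cells the mean TPM and the share of cells were 838 and 89% for Inhba, an activin subunit, 837 and 83.4% for Rspo4, 815 and 89.6% for Wif1, 522 and 88.4% for Sostdc1, 190.5 and 81% for Fgf10, 183.1 and 79.5% for Bmp3, an atypical BMP, 150.1 and 86.9% for Fgf7, 125.2 and 75.1% for Dkk2, a Dickkopf antagonist, 123.1 and 89% for Rspo1, 88.1 and 70.9% for Rspo3, 86.9 and 68.5% for Notum and 57.6 and 79.2% for Bmp4. Of the 25 dermal papilla genes, 20 were seen in at least 50% of these cells, among them Corin, a membrane protease (573 and 82.8%). P30 matrix cells gave 203.6 and 78.4% for Kitl, 21.3 and 71.6% for Wnt5a, 10.2 and 79.7% for Wnt4 and 9.49 and 53.6% for Wnt3. Telogen bulge cells gave 146.4 and 100% for Dkk3, 134.4 and 97.4% for Nbl1, a DAN family antagonist, 110.3 and 92.3% for Fst, 98.1 and 94.9% for Sema3c, a semaphorin, 57.7 and 92.3% for Fgf1 and 44.5 and 84.6% for Grem1. Telogen germ cells gave 143.3 and 95.8% for Pdgfa and 86.5 and 87.3% for Cxcl12, and P25 to P27 matrix cells 19.2 and 43.2% for Wnt7b, an epithelial WNT.

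Receptors were shared more widely than most lists of ligands and antagonists: 20 to 25 of 39 were seen in at least 50% of the cells of each of the 6 types. For WNT ligands this held for 0 to 5 of 21. Exceptions were 8 of 14 BMP and TGF-beta ligands in the dermal papilla and 6 of 10 BMP inhibitors in the telogen bulge. Egfr, the EGF receptor, was seen in 100% of telogen bulge and 95.3% of P30 matrix cells, and Bmpr1a, a type I BMP receptor, in 88.8% of first-stage germ and 94% of P30 matrix cells. Pdgfra, the receptor of PDGF-A, stood at 90.2 and 89.3% in the dermal papilla, where Ednrb, an endothelin receptor, stood at 29.2 and 69.4%. Lgr6 stood at 89 and 82.9% in the P25 to P27 matrix and 2.67 and 9.90% in the P30 matrix, and Fzd10, a WNT receptor, at 9.84 and 63.8% in the latter. Of the 750 pairs of a gene and 1 of the 6 types, 29.6% reached 50% of the cells and 28.4% a mean TPM of 10.

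**Figure D4:**
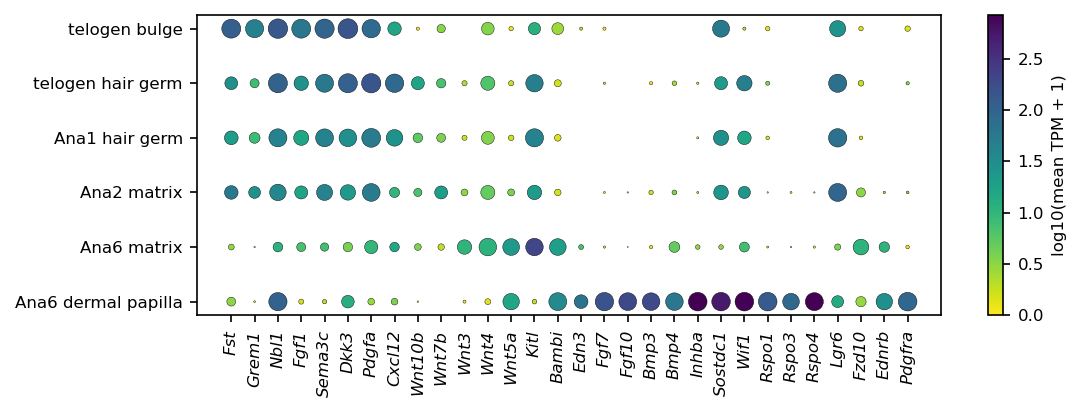
Ligands, antagonists and receptors by the authors' types. Dot area is the share of cells at a TPM of 1 or more, and strains and ages differ between the P30 types and the others.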

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

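All tests in this part were chosen only after the values they explain had been seen.

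The signal of ERCC spike-in molecules differed between groups. They were compared in no result above, yet they count in the total of each TPM column and so enter every difference. They made up a median 14.4% of TPM in P21 bulge cells, 10.7% in P21 hair germ cells, 4.24% in P23 to P24 germ cells, 8.53% and 6.46% in P25 to P27 germ and matrix cells, 8.23% in dermal papilla cells and 0.709% in P30 matrix cells. The amount added per well is not in the labels, so the shares were not turned into RNA per cell and no explanation was tested.

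Processed pseudogenes of ribosomal proteins, which no gene list holds, marked whole plates. Rpl3-ps1 was seen in 93.2% of the cells of plate 902hg, which holds all P23 to P24 germ cells, in 0% to 2.94% of the cells of each other P21 to P27 plate, and in 90.7% to 98.7% of the cells of each P30 hair bulb plate and 81.6% to 96.6% of each dermal papilla plate. Rps2-ps13 was seen in 98.8% of the cells of the hair bulb plate P2-1 and in 4.05% to 6.67% of those of the other 4 hair bulb plates. Rps3a3, Rps3a2 and Rpl17-ps5 divided plate P2-1 itself: 40 cells had none of the 3, 28 had all, 10 had 1 and 3 had 2, while Rps3a3 was seen in 92% to 98.6% of the cells of each of the other 4 plates.

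A processing difference that covers all of plate P2-1 cannot divide its cells whatever the values, so the test made of it decides nothing. In it, Rps2, of another family, differed by -4.08 (-4.89 to -3.24 over resampled cells) between carriers and the other cells. Carriers are the 31 cells with at least 2 of the 3 pseudogenes, and the others number 50. Rps2 summed with its pseudogenes Rps2-ps13 and Rps2-ps10 differed by only -0.15. For Rps2-ps13, seen in nearly all cells of the plate, a processing difference stays open. Mice whose genotype differs from the reference genome may explain the division. In carriers the parent genes Rps3a1 and Rpl17 changed by -1.07 and -0.61, as reads of a variant copy would move from parent to pseudogene. Any other cause that moves reads between these copies would give the same falls, so they do not single out genotype. Parent and pseudogenes summed moved less, by -0.28 and -0.16. Which mice lie behind a plate is not in the labels, and no biological explanation was tested. For Rpl3-ps1, Rpl3 was lower by 0.81 in cells of plate 902hg and the sum by 0.06, and as this plate holds all P23 to P24 cells, genotype and age cannot be told apart there.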

How the results depend on the processing

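The pseudocount, the ratio of mean TPMs, the filters on cells and list genes, the rescaling without the 20 highest genes, the TPM threshold, the highest other type as reference and leaving out plates were chosen before the data were examined, and rescaling without spike-in, ribosomal RNA and mitochondrial transcripts, subtraction of the median gene, subsets by markers, and all alternatives for further lists, named genes and P30 against P25 to P27 were chosen after. With no replicates, a list or gene value was counted as kept when it had the same sign and lay within 1.5 times, a share when it lay in its 95% interval, and a count within 1.5 times. For 12 planned list medians, 80 values were kept, 48 moved and 13 changed sign. For 37 further list medians 72.3% of values were kept, 27.4% moved and 1 changed sign, and for the named genes 1673 were kept, 453 moved and 6 changed sign. For the 6 planned shares 23 were kept and 8 moved. Where no cause is given below, the cause was not tested.

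With a pseudocount of 10 the median of bulge genes in P21 bulge over germ went from 1.49 to 0.93, of hair germ genes in germ over bulge from 1.21 to 0.60, and of G2/M genes from 1.42 to 0.63 (P23 to P24 over P21 germ) and from -1.23 to -0.54 (P25 to P27 matrix over P23 to P24 germ). In the latter comparison matrix genes gave 0.0353 and bulge genes 0.0168 in place of 0.08 and -0.26, and matrix genes over P25 to P27 germ 0.12 in place of 0.31. By type, bulge genes gave 1.23 (telogen bulge, 2.196), hair germ genes 0.37 (telogen germ, 0.83) and -0.16 (first-stage germ, 0.05) and G2/M genes 0.48 (first-stage germ, 1.11). A larger pseudocount shrinks differences by construction, and the cause of the 2 changes of sign was not tested.

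With a pseudocount of 0.1 the same medians were 1.90 for hair germ genes at P21, 2.51 and -2.17 for G2/M genes, -0.000814 for matrix and -0.43 for bulge genes in P25 to P27 matrix over P23 to P24 germ, and 0.62 for matrix genes over P25 to P27 germ. By type they were 1.38 and 0.46 for hair germ genes (telogen and first-stage germ), 1.94 for G2/M genes and 0.0125 for matrix genes in second-stage matrix (0.04).

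With the log2 ratio of mean TPMs they were 0.61 for bulge genes at P21, 3.31 and -2.11 for G2/M genes, 0.42 for matrix and 0.13 for bulge genes in P25 to P27 matrix over P23 to P24 germ, and 0.93 for matrix genes over P25 to P27 germ. By type they were 1.24 for bulge, 2.73 for G2/M, -0.52 for hair germ genes in first-stage germ and 0.47 for matrix genes. Gli1 in P23 to P24 over P21 germ went from 0.23 to -0.19, and Lef1 in P25 to P27 matrix from -0.55 to 0.17 over P23 to P24 and from -0.80 to 0.41 over P25 to P27 germ. The cause was not tested.

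Among cells with at least 2000 genes, matrix and bulge genes in P25 to P27 matrix over P23 to P24 germ gave 0.0491 and -0.40, hair germ genes in first-stage germ 0.16 and matrix genes in second-stage matrix 0.0202. Rescaled without the 20 highest genes, bulge genes gave -0.0875 in the former comparison, and the 2 type medians were 0.31 and 0.0832. Rescaled without spike-in, ribosomal RNA and mitochondrial transcripts, matrix genes gave 0.11 and the 2 type medians 0.31 and 0.0879. Minus the median gene, matrix genes gave 0.37 and bulge genes 0.0388. Rescaling moved the median gene itself from -0.06 to 0.14 between P21 and P23 to P24 germ and from 0.34 to 0.82 between P25 to P27 and P30 matrix. Against the highest other type, hair germ genes gave -0.0589 (telogen germ) and -0.92 (first-stage germ), matrix genes -0.0530 and hedgehog response genes -0.0110 (0.66), since a maximum is never below a mean.

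Leaving out 1 plate at a time, matrix genes ran from 0.0166 (without 920mat) to 0.13 (914mat) and bulge genes from -0.43 (915mat) to -0.0128 (914mat, and -0.0854 without 920mat) in P25 to P27 matrix over P23 to P24 germ. Krt15 ran from -1.44 to 0.17 (without 920mat; -0.83 with all). Over P25 to P27 germ, matrix genes ran from 0.23 to 0.78 and Stmn1 from -1.31 to 2.80, with 0.78 and -1.31 without 913hg, which leaves 2 germ cells. In first-stage germ, without 902hg the G2/M median was -0.12 (highest 1.33) and Uhrf1 -0.46 (highest 3.11), since this plate holds all P23 to P24 cells. Hair germ genes there ran from -0.12 (902hg; -0.02 without 913hg, -0.03 without 920mat, 0.01 without 914mat) to 0.14 (915mat), and matrix genes in second-stage matrix from 0.0106 (913hg) to 0.23 (902hg and 914mat).

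At a TPM of 10 or more Mki67 was seen in 0% of P21 germ, 35.6% of P23 to P24 germ, 7.04% of P25 to P27 matrix, 0.297% of dermal papilla and 33.9% of P30 matrix cells, and above 0 in 8.31% and 65.4% of the last 2. In P25 to P27 matrix its share ran from 6.11% (without 920mat) to 17.4% (914mat). The share of pairs of ligand or receptor and type fell from 29.6% to 16.3% at a TPM of 10, as a stricter limit must lower it, and from 28.4% to 16.3% with the median in place of the mean TPM, where the cause was not tested. The planned comparisons by type of lineage lists in the P30 hair bulb and of dermal papilla genes in the dermal papilla table could not be made, as each table holds 1 type. Depth is not recorded in TPM, so what it limits was read from the genes seen per cell only.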

Other observations

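All tests in this part, and the clusters, were chosen only after the data had been seen.

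Cells of the P30 hair bulb, 1 type in the authors' annotation, fell into clusters that held known marker genes. Some expressed Lgr5 and Krt15, genes of follicle stem cells, with Fgfr3, a receptor for FGFs. Others expressed Tchh, trichohyalin, and Krt75, genes of the medulla, together with Gpnmb, which was also high in a cluster with little gain of melanocyte genes. Histones, and Ube2c and Cdk1, genes of division, set 2 clusters apart. Of the smaller clusters, 1 carried the smooth muscle genes Acta2, Myh11 and Myl9, and another Sox8, a transcription factor, Mest, an imprinted gene, Pmp22, a myelin protein, Col3a1, a fibrillar collagen, and markers of several other types.

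In the P30 dermal papilla, Rspo3 and Rspo2, R-spondins that amplify WNT signals, were among the top genes of different clusters. Corin and Notum, genes of the papilla, were joined by Col13a1, a transmembrane collagen, and Penk, proenkephalin. The agouti gene a, which switches pigment type, went with Mmp3, a matrix protease, and a small cluster carried Acta2, Ntn1, netrin 1, and Lrrc15, a gene of activated fibroblasts.

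The hair bulb gave 8 clusters of cells with at least 2000 genes (6 and 9 at the 2 other resolutions). Cluster 5 (42 cells) had Krt15 in 100% against 23.7% of the other cells and Lgr5 in 95.2% against 4.45%, with outer root sheath and bulge genes 3.97 and 2.95 above the mean of the other clusters. Clusters 1, 3, 4 and 6 (78, 57, 53 and 34 cells) had medulla genes 2.66, 3.49, 2.95 and 2.46 above it, with Krtap8-1, a hair keratin associated protein, in 75.6% against 30.2% of cells for cluster 1 and Fabp4, a fatty acid binding protein, in 98.1% against 49.7% for cluster 4. Melanocyte genes went with clusters 1 and 3 (1.83 and 1.66) but not 4 (0.14), and were low in clusters 2 and 5 (-1.39 and -2.06). Clusters 2 and 6 (71 and 34 cells) had G2/M genes at 2.95 and 4.79, Mki67 in 98.6% and 100% of cells and Ube2c in 100% against 31% for the latter. Cluster 7 (23 cells) had Myh11 in 100% against 0.562% of cells, with dermal sheath genes at 8.29 and pericyte genes at 6.56. Cluster 8 (21 cells) had Sox8 in 95.2% against 4.19%, with muscle progenitor genes at 5.197, Schwann cell genes at 2.12 and dermal fibroblast genes at 1.40. In clusters of shuffled hair bulb values the top gene lay up to 3.14 above the mean of the others. Myh11 in cluster 7 lay far above that (9.93), Krtap8-1 in cluster 1 less so (4.90), and Dct in cluster 1 near it (3.27). These genes were picked from the cells that made the clusters, so the gaps describe the clusters only.

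The dermal papilla gave 6 clusters of such cells (5 and 8 at the other resolutions). Rspo3 had a mean TPM of 212.8 against 61.2 in cluster 1 (73 cells), a was seen in 85.9% against 27.9% of cells in cluster 2 (71 cells), Rspo2 stood at 100 against 37.5 in cluster 3 (58 cells), where dermal papilla genes were 0.98 higher, and Col13a1 at 85.6 against 19.8 in cluster 4 (56 cells). Cluster 5 (27 cells) had Igfbp3, a binding protein of insulin-like growth factors, at 486 against 59.4. Cluster 6 (19 cells) had Ntn1 in 100% against 4.56% of cells, dermal sheath genes 2.89 higher and dermal papilla genes at -1.46. Shuffled values also divide under this method, so the number of clusters carries no weight. In clusters of shuffled papilla values the top gene lay up to 2.35 above the mean of the others, less than Rspo3 (4.57) and Rspo2 (4.68) in the measured ones. These genes were picked from the cells that made the clusters, and a gradient along the papilla would give such gaps too, so they do not show separate populations.

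Dct, a pigment enzyme, was seen in 80.7% (76 to 84.7) of the hair bulb cells with at least 6 keratinocyte markers. Among cells with fewer keratinocyte markers and at least 2000 genes, it was seen in 34.9% (21 to 50.9). For Dct alone this argues against free RNA alike in every well. For the marker list free RNA stays open, as the intervals overlap. At least 5 melanocyte markers were seen in 39% (33.7 to 44.4) of the former cells and in 23.3% (11.8 to 38.6) of the latter. More genes detected is argued against, as 38.1% (27.7 to 49.3) of the 84 keratin-positive cells with the fewest genes and 36.9% of the 84 with the most had at least 5 melanocyte markers. Melanocyte material in the same well may explain it: 20 genes outside the list, such as Trpm1, Gpr143 and Mlph, genes of pigment cells, reached a median 0.321 of their level in 10 melanocyte-like cells, beside 0.244 for the list. A first choice of 20 genes gave 0.00733 and held pericyte genes. The second was made after this was seen and still held 1 of them, Rgs5 (0.00277). The 10 melanocyte-like cells had a mean TPM of 897 for Acta2 and 387 for Rgs5, so they were not free of smooth muscle or pericyte transcripts. The test therefore weighs little, and no biological explanation, such as expression by the cells of clusters 1 and 3 themselves, was tested.

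Of the hair bulb cells, 12.5% (48 cells; 4.94% to 20% by plate) had under 6 keratinocyte markers. Wells with little RNA stay open for some of them: these cells had 0.779 times the genes of the others and a median spike-in share of 1.199% against 0.668%, and all 5 hair bulb cells with under 2000 genes are among them. Cells of another type in the sort may explain others. Of the 48 cells, 39.6% (25.8 to 54.7) had at least 3 pericyte markers, against 2.68% of the other cells. At least 5 dermal sheath markers were seen in 37.5% (24 to 52.6) against 6.55%. Either 3 pericyte or 5 muscle progenitor markers were seen in 64.6% (49.5 to 77.8) against 5.36%. The muscle progenitor list and the numbers of markers were chosen after the data were seen, so these shares are no independent evidence. Acta2 was seen in 68.8% of the 48 cells and Pax7, a factor of muscle stem cells, in 25%. No biological explanation was tested, as the design names no second population there. Without these cells the share of P30 matrix cells with Mki67 was 57.4%.

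At least 9 of the 18 bulge genes were seen in 100% of P21 bulge cells, 74.6% of P21 germ, 74% of P23 to P24 germ, 87.5% of P25 to P27 germ, 48.2% of P25 to P27 matrix, 11.2% of P30 matrix and 3.26% of dermal papilla cells.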
